A study of Chlamydomonas reinhardtii with 4 samples.

How the data were processed

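RNA of Chlamydomonas reinhardtii was sequenced from 4 cultures: the wild type D66 and the mutant ars11, each in sulfur-replete medium and after sulfur deprivation. Per the labels, cells grew in an acetate medium (TAP) under continuous light. The replete samples were taken at 0 h, just before transfer, and the deprived samples 6 h after cells were washed and moved to the same medium without sulfur. The comparison of media therefore also holds the washing and 6 h of time. Per the labels, the libraries were read as 35-base sequences in 11 Solexa lanes, and the standard Solexa pipeline was used. The aligner, the genome build, the gene models and the program that made the gene values are not given in the sources used here.

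The 4 groups were taken from the strain and medium that the labels give. Each group holds 1 library, so no difference between groups has a replicate check. Lanes are runs of the same library and were not treated as replicates.

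The authors deposited RPKM values (reads scaled by gene model length and library depth) for 14599 gene models, 1 value per library, and per the file headers these are transcript abundances. The values fit an average over lanes of reads scaled to the lane totals. Of 220 gene models with both ars11 values above 0 and up to 0.5 RPKM, 35 had a ratio within 0.001 (natural log) of that of 1 read against 1 read at the lane totals, against at most 6 at 50 shifted positions. Per the file headers, the authors' deposited table also holds log2 ratios of the sequencing values, log2 ratios in columns marked M or Q with a time, and p-values of the authors' comparisons. What M and Q stand for, and the test behind the deposited p-values, are not given in the sources used here. The authors also deposited a file of aligned read positions for each lane, and reads were counted here from these files, per the file headers 1 alignment in each line.

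Depth was taken from the aligned reads of each lane. The D66 replete library held 21169585 reads in 4 lanes, D66 deprived 15652398 in 3 lanes, ars11 replete 6503999 in 2 lanes and ars11 deprived 7019095 in 2 lanes. A gene model with 1000 bases at 5 RPKM corresponds to 105.8, 78.3, 32.5 and 35.1 reads in these libraries. In such a gene, 3 reads correspond to 0.142, 0.192, 0.461 and 0.427 RPKM. These figures cover counting error only, and gene lengths are not given in the sources used here.

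Values were compared as log2((RPKM + 1)/(RPKM + 1)) in 4 comparisons: deprived against replete in D66, deprived against replete in ars11, ars11 against D66 in replete medium, and ars11 against D66 in deprived medium. A gene entered a comparison where its higher library reached 5 RPKM. A gene was counted as risen or fallen where the log2 change was at least 2 in size (4-fold). The difference of responses was the log2 change in ars11 minus that in D66. No fold is printed against a library in which a gene is listed at 0. Of the gene models, 998 were listed at 0 in all 4 libraries, and 9793 reached 5 RPKM in at least 1 library. For 9683 gene models the deposited names gave no function.

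Genes were named by a rule. For each comparison, the 10 largest rises and the 10 largest falls among genes with a name or a described function are given, together with the largest 2 each way among genes without one, by identifier. For each gene list, the largest rise, the largest fall and the most highly expressed member could be named. For the difference of responses, the 10 largest shortfalls and the 5 largest excesses in ars11 are given. Genes named in a comparison outside this rule were chosen after their values were seen, and are listed as such in the text of that comparison. The comparisons, the size rule, the filter, the naming rule and 26 gene lists were chosen before the data were examined. Another 7 lists were chosen after seeing the data. Gene names and identifiers are those of the deposited table.

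The 26 lists covered sulfate uptake, arylsulfatase and sulfonate use, sulfate assimilation and cysteine synthesis, methionine and thiol metabolism, extracellular and cell wall proteins, the light-harvesting antenna, stress-related LHC proteins, the photosystem core, carbon fixation, chlorophyll synthesis, cytosolic ribosomal proteins, plastid ribosomal proteins, proteasome with ubiquitin and autophagy, redox defence, heat shock and chaperones, starch, sulfolipid and storage lipid, polyphosphate and vacuole, hydrogenase and fermentation, phosphorus starvation, nitrogen starvation, gamete and zygote markers, flagella and microtubules, histones and cell cycle, signalling of sulfur deprivation, and housekeeping. They matched 1420 gene models by symbol or keyword. The 7 later lists were SNARE, ESCRT and retromer subunits, U snRNA gene models, low-oxygen markers, copper-responsive genes, low CO2 inducible genes, the heat shock protein 22 family, and TROVE domain with 2 5 oligoadenylate genes. For each list, the median log2 change was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries and is not a test. After seeing the data, medians were also taken over the other genes named low CO2 inducible and over sulfate uptake without the filter. A median below percentile 2.5 or above percentile 97.5 is called outside the central range. Some gene models share names or have near-equal values, and their sequences were not compared here. How the authors placed reads that match several models is not given in the sources used here. Past the filter, 9 pairs of gene models shared all 4 values.

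Because the lane files hold positions and not genes, and no gene coordinates were used, lanes were compared over 118214 windows of 1000 bases. Of these, 38549 reached 5 RPKM, computed from the read totals, in at least 1 library. Windows were counted by the same size rule as genes.

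Alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 20 RPKM, a 2-fold size rule, 3 scalings of the RPKM values (TMM, median of ratios, upper quartile), list matching by symbol only, random lists not matched on expression, the difference of responses with genes at least 2-fold higher in deprived D66, the agreement of responses over genes at least 2-fold changed in either strain, and each lane left out in turn over windows. The TMM and median-of-ratios factors came from edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3, and were used only to rescale values. Chosen after seeing the data were lists without 27 members whose name states another protein, windows with subsets of the D66 lanes, windows with full-length alignments only, windows with D66 lanes thinned to the ars11 reads, and the scalings of the 7 later lists. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

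The steps were tested on simulated reads with known changes, 50 genes for each fold size and direction, each gene taken as 1000 bases long. In the D66 deprivation comparison (8193 genes), 50 of 50 genes raised 8-fold and 43 of 50 lowered 8-fold were counted. In the ars11 deprivation comparison (8637 genes), these were 50 and 46. In the strain comparison in replete medium (8287 genes) they were 50 and 45, and in deprived medium (7858 genes) 50 and 41. Of genes changed 3-fold, 0 of 50 were counted in each direction of each comparison, and 0 unchanged genes were counted. The simulated reads held counting error only, without variation between lanes, libraries or cultures. These counts therefore check the size rule and do not measure false calls in the real libraries. Of 200 random lists of unchanged genes, given added random spread, 8, 6, 14 and 9 lay outside the central range in the same order of comparisons.

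Left out were gene values recounted from the lane files, since no gene coordinates were used, and read-based intervals for single genes, since reads per gene are not given in the deposited table. The spread between lanes is given over windows and not for each gene.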

Results

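Transcripts of the green alga Chlamydomonas reinhardtii were measured by RNA sequencing in 4 libraries. D66 is the wild-type strain and ars11 is a strain carrying a lesion in SNRK2.1, a protein kinase of the SnRK2 type. Each strain was sampled in sulfur-replete medium (0 h) and 6 h after transfer to medium without sulfur. There is 1 library in each group, so there are no replicates. The values below describe these 4 libraries, and no test across genes was made.

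The libraries were read in 11 lanes. D66 replete held 21169585 aligned reads in 4 lanes and D66 deprived 15652398 in 3 lanes. The ars11 replete and deprived libraries held 6503999 and 7019095 aligned reads in 2 lanes each. At 5 RPKM, the lowest level at which a gene entered a comparison, a gene model of 1000 bases corresponds to 105.8 reads in D66 replete and 32.5 in ars11 replete. Where the lower library lies below 1 RPKM, the size of a fold is set largely by the added 1 RPKM, and both values should be read.

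The lanes of each ars11 library differed about as much as counting error allows. Over windows of 1000 bases, the mean chi-square per degree of freedom was 1.01 and 1.02 in replete and deprived ars11, with 5.19 and 5.23% of windows beyond the Poisson limit. In replete and deprived D66 the mean was 5.23 and 4.43. The medians were lower, at 1.44 and 1.06, and 27.4% of windows in replete D66 lay beyond the limit. In replete D66, 89 windows were at least 4-fold apart between lanes 1 and 2 and lanes 3 and 4, and in 89 of these the value was higher in lanes 3 and 4. The deprivation folds from D66 lanes 1 and 2 and from the other D66 lanes had a Pearson r of 0.905 over windows. By the 4-fold rule, lanes 1 and 2 gave 932 windows higher and the other lanes 766, with 668 in both. For lower windows these were 980, 704 and 561, so the D66 calls depend in part on the lanes used. Reads aligned over 35 bases made up 80.9 to 81.1% in the deprived ars11 lanes and 87.7 to 90.4% in the deprived D66 lanes. Apart from rare lengths, alignments shorter than 35 bases reached 32 bases in every D66 lane and 30 in every ars11 lane. This difference in trimmed lengths goes with strain, and its source is not known.

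**Figure D1:**
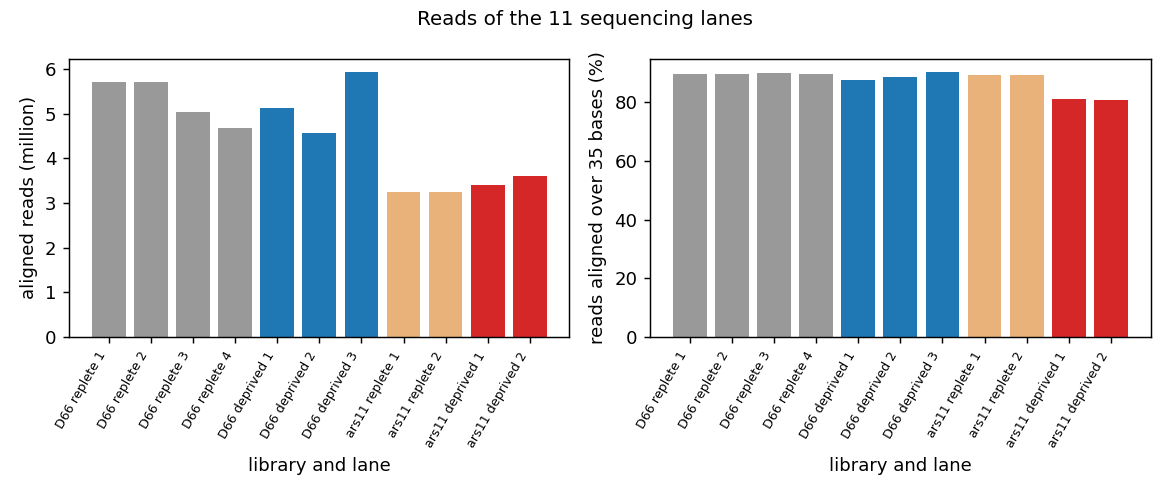
Aligned reads (M reads) and reads aligned over 35 bases (%) in each of the 11 lanes, 1 bar per lane, coloured by library. The ars11 lanes hold fewer reads than the D66 lanes, and the deprived ars11 lanes have the lowest share of 35-base alignments (80.9 and 81.1%).

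The gene named in the design, SNRK2.1, could not be followed: 0 gene models carry that name, and its transcript was not analysed here. Among kinases and regulators of the sulfur response, SAC1 (131143), a membrane protein acting upstream of the response, was at 16.6, 16.5, 14.6 and 9.51 RPKM in D66 replete, D66 deprived, ars11 replete and ars11 deprived. SAC3 (185806), an Snf1-like kinase, was at 60.8, 73.8, 59.1 and 92.8 RPKM. SNRK2.6 (131583) was at 17.9 and 16.5 RPKM in D66 and at 19.9 and 56.8 RPKM in ars11, and SNRK2.7 (153921) at 33.4 and 31.1 RPKM and at 42.8 and 92.2 RPKM. These 4 genes formed the signalling list. Its median log2 change with deprivation was -0.05 in D66, a sign that turned under each of the 3 other scalings, and 0.87 in ars11. None of the 4 passed 4-fold in any comparison.

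What sulfur deprivation does in the wild type was asked by comparing deprived with replete D66. The largest rises included the extracellular proteins ECP88 and ECP76, the arylsulfatase ARS1 and the light-harvesting gene LHCBM9. Among the lists, sulfate uptake and sulfate assimilation had high medians, while the extracellular and cell wall list as a whole was mixed. Plastid ribosomal, chlorophyll synthesis and methionine lists had low medians. Of 8679 genes, 161 rose (94 of them with a name) and 263 fell (193 with a name). The median of all genes was -0.12, which TMM, median-of-ratios and upper-quartile scaling shift by 0.15, 0.15 and 0.19. The share of risen genes was 38.0% and became 49.2, 49.2 and 50.6% (192 higher and 198 lower, 192 and 198, and 197 and 192), so the excess of falls depends on the scaling.

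The largest rise was that of ECP88 (137329), an extracellular protein, from 0.218 to 2295 RPKM (log2 10.88). Other extracellular proteins were ECP76 (130684; 0.542 to 899 RPKM, 9.19), ECP 56 (194201; 0.802 to 317, 7.46) and ECP 61 (119420; 0.765 to 268, 7.25). LHCBM9 (184479), a light-harvesting protein of photosystem II, rose from 20.6 to 21455 RPKM (9.96). Arylsulfatase ARS1 (205496), which releases sulfate from organic esters outside the cell, rose from 1.87 to 2717 RPKM (9.89). The vanadium haloperoxidases HAP2 (143696; 3.07 to 1044 RPKM), HAP1 (168785; 3.19 to 739, 7.46) and HAP3 (182794; 10.3 to 1456, 7.01) and the taurine dioxygenase TAUD1 (127464; 10.1 to 1417, 6.99) complete the 10 largest named rises. Among gene models without a described function, 184282 rose from 0.306 to 265 RPKM (7.67), and 171504 was listed at 0 in replete D66 and at 102 RPKM in deprived D66.

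The largest named fall was that of FAP24 (196738), a flagellar associated protein, from 509 to 10.3 RPKM (log2 -5.50). Next were a SurE survival protein (144281; 21.0 to 0.163 RPKM, -4.24), a nucleoside diphosphate kinase (180172; 47.8 to 2.09, -3.98), the cobalamin synthase CobS (146651; 38.4 to 1.55, -3.95), MOT38 (151348; 20.4 to 0.397, -3.94) and the glutaredoxin GRX6 (195615; 27.9 to 0.889, -3.94). AK4 (133184), an adenylate kinase, fell from 85.6 to 5.26 RPKM (-3.79), and a ribosome recycling factor (119597) from 57.6 to 3.25 RPKM (-3.79). METE (154307), the cobalamin-independent methionine synthase, fell from 606 to 45.5 RPKM (-3.70). THICa (192720), of thiamine synthesis, fell to 6.45 RPKM (-3.69). How reads are divided between it and the like-named THICb (196900) is not known. The largest fall without a name was 160533, from 75.4 RPKM (-4.67), while 181249 was at 21.9 RPKM and listed at 0 after deprivation.

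Sulfate uptake is the first step of sulfur use. Of 11 measured genes, 8 were at least 2-fold higher (6 of them at least 4-fold), 1 lower and 2 within 2-fold. The median was 2.37, at percentile 100 among 10000 matched random lists, as a description of these libraries. The animal-type transporters SLT1 (205502; 20.2 to 2341 RPKM, log2 6.79) and SLT2 (205501; 16.8 to 1339, 6.23) and the plant-type transporter SULTR2 (150514; 3.73 to 152, 5.01) rose most. SLT3 (205500) was at 21.4 and 6.14 RPKM. The chloroplast importer subunit SULP1 (128906) rose from 27.8 to 147 RPKM (2.37). AOT4 (206105), matched to this list, is named as a polyamine and amino acid transporter, and it rose from 21.4 to 311 RPKM; without it the median was 1.90. In the arylsulfatase and sulfonate list, 4 of 6 genes rose and 2 lay within 2-fold (median 5.60, percentile 100), with TAUD2 (77600) rising from 16.8 to 632 RPKM (5.15). ARS5 (205499) was at 10.8 and 6.05 RPKM.

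In sulfate assimilation and cysteine synthesis, 9 of 16 genes were at least 2-fold higher (6 of them 4-fold), 1 lower and 6 within (median 1.40, percentile 100). The genes with 4-fold rises include OASTL4a as 2 models with equal values (183351 and 189320). Those within include SAC1 (131143) and SPCS (117639), whose names state another protein. The list holds these members in each comparison. Serine acetyltransferase SAT1a (205985), which makes the acceptor of sulfide, rose from 22.8 to 794 RPKM (log2 5.06), and its copy SAT1b (187821) shows nearly equal values, and how reads are divided between them is not known. The O-acetylserine lyase OASTL4b (205986) rose from 71.9 to 894 RPKM (3.62) and ATP sulfurylase ATS2 (133924) from 36.3 to 254 RPKM (2.77). ATS1 (196910), the most highly expressed, was at 723 and 2137 RPKM, and SIR3 (188119) at 13.1 and 5.40 RPKM. The methionine and thiol genes went the other way: 8 of 13 were at least 2-fold lower and 0 higher (median -1.34, percentile 0.07). SAH1 (129593) fell from 1298 to 152 RPKM (-3.09) and METM (182408), which makes S-adenosylmethionine, from 2288 to 526 RPKM (-2.12). In sulfolipid and storage lipid, whose median of -0.11 turns positive under each other scaling, SQD1 (27658) was at 102 and 336 RPKM and PLSB1 (205741) fell from 54.5 to 11.6 RPKM (-2.14). Of 46 extracellular and cell wall genes, 6 were at least 2-fold higher, 7 lower and 33 within (median 0.13, percentile 98.4), and PHC5 (196406) fell from 117 to 12.5 RPKM (-3.12).

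All 36 measured plastid ribosomal genes were at least 2-fold lower, 28 of them at least 4-fold (median -2.57, percentile 0). PSRP 3 (195633) fell from 209 to 16.2 RPKM (log2 -3.61), PRPL7/L12 (99271) from 581 to 52.0 RPKM (-3.46), and PRPS1 (79955) was at 356 and 158 RPKM. Of 69 cytosolic ribosomal genes, 66 lay within 2-fold (median 0.19). In chlorophyll synthesis, 20 of 25 genes were at least 2-fold lower (10 of them 4-fold; median -1.88, percentile 0); GSA (138524) fell from 151 to 12.1 RPKM (-3.54), whereas SUMT1 (191432) rose from 11.5 to 53.8 RPKM (2.13). In the photosystem core, 20 of 33 genes were at least 2-fold lower and 0 higher (median -1.21), with a PSBP-like protein (127879) falling from 67.7 to 7.76 RPKM (-2.97). In the antenna, 15 of 28 genes were at least 2-fold lower and 5 higher (median -1.10, percentile 0.04); a chlorophyll a/b binding protein (182724) fell from 77.2 to 15.7 RPKM (-2.23), and LHCBM1 (185533) was at 8019 and 5425 RPKM. The stress-related LHC proteins, which share 5 genes with the antenna list, were higher in 5 of 8 genes (median 1.94): ELIP3 (148916) rose from 5.68 to 42.3 RPKM (2.70).

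Of 56 carbon fixation genes, 8 were at least 2-fold higher and 15 lower (median -0.35). The 8 include SBP1 (182359), a sulfate transporter subunit also counted in sulfate uptake, and the 15 include PGK1 as 2 models with equal values (132210 and 36313); the list holds these members in each comparison. In this list the carbonic anhydrase CAH9 (196834) rose from 62.1 to 1952 RPKM (log2 4.95). Among housekeeping genes, 16 of 28 were at least 2-fold lower (median -1.29, percentile 0.01), with the initiation factor EIF3D (181144) falling from 102 to 14.9 RPKM (-2.70). The initiation factors EIF3B (128636; -2.68) and EIF3E (132936; -2.42) also fell, while RACK1 (105734; 0.19) and TUB1 (129876; -0.07) lay within 2-fold. Of 92 heat shock and chaperone genes, 27 were lower and 3 higher (median -0.53, percentile 0.02); the plastid chaperonin CPN60A (24547) fell from 190.3 to 16.6 RPKM (-3.44). In histones and cell cycle, 20 of 41 genes were lower and 0 higher (median -0.96, percentile 0). In hydrogenase and fermentation, 6 of 17 were higher and 0 lower (median 0.57, percentile 99.9), and a zinc alcohol dehydrogenase (191379) rose from 6.61 to 36.9 RPKM (2.31). For nitrogen starvation, 3 of 21 were higher (median 0.30, percentile 98.8), with NII1 (192085) rising from 1.79 to 11.8 RPKM (2.20). For phosphorus starvation, 1 of 12 was higher (median -0.29): LPB1 (196477), named for low-phosphate bleaching, rose from 98 to 1711 RPKM (4.11). LPB1 is listed with whole numbers in all 4 libraries (33 and 39 in replete and deprived ars11). Whether these values are RPKM like the others is not known. Flagellar genes had a median of 0.29, with 322 of 336 within 2-fold. The gamete and zygote list (6 genes) had a median of 0.61, and of 0.23 without HAP2. Redox defence (66 of 80 within 2-fold, median -0.17), starch (27 of 31, -0.10), polyphosphate and vacuole (10 of 13, -0.16) and proteasome, ubiquitin and autophagy (62 of 69, -0.18) had medians near 0. In the last list, 5 genes were at least 2-fold higher, 4 of them autophagy genes: APG12 (194981; 7.79 and 21.1 RPKM), ATG8 (59275; 113 and 239), APG3 (186904; 31.8 and 67.2) and APG7 (114160; 5.47 and 12.8). The sign of the starch median turns under each other scaling, and that of the polyphosphate and proteasome medians under upper-quartile scaling. In this comparison SLT2, SULTR2, SULP1, AOT4, TAUD2, SAT1b, OASTL4b, ATS2, SAH1, ELIP3 and THICb were named outside the naming rule, after the values were seen. So were ATG8, APG3, APG7, SBP1, PGK1, OASTL4a, SAC1, SPCS, EIF3B, EIF3E, RACK1 and TUB1. Sampling at 0 h before and 6 h after a wash means that deprivation cannot be separated here from handling and time.

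**Figure D2:**
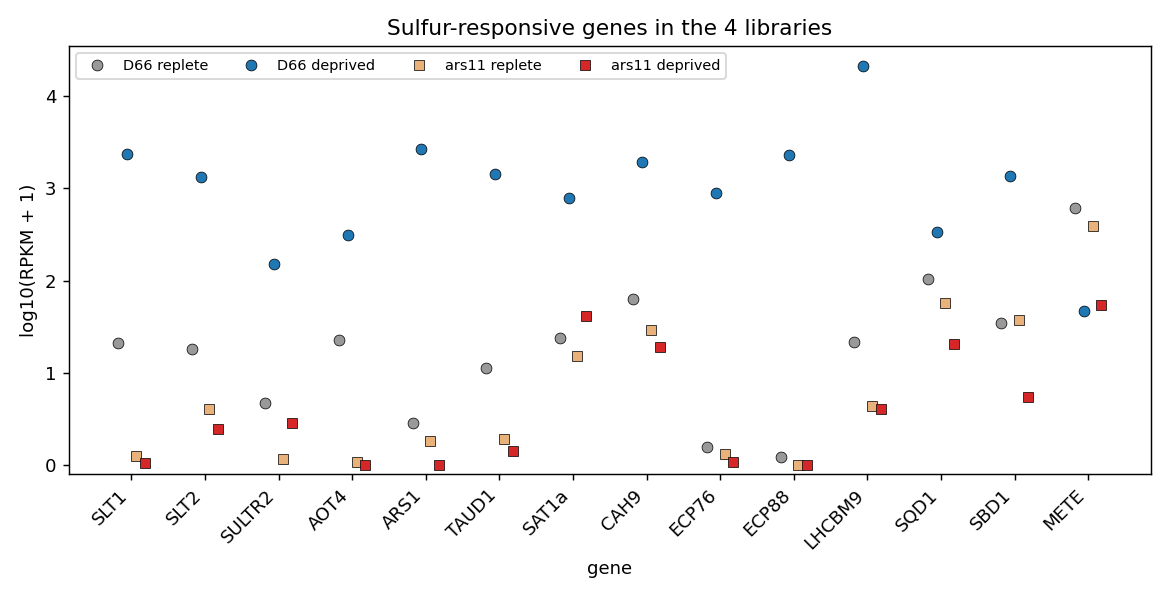
Expression, log10(RPKM + 1), of 14 genes in the 4 libraries, 1 point per library. SLT1, SLT2 and ARS1 reach 2341, 1339 and 2717 RPKM in deprived D66; in deprived ars11 SLT1 and SLT2 are at 0.0489 and 1.46 RPKM and ARS1 is listed at 0.

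How the mutant responds was asked by the same comparison in ars11. The sulfur uptake genes that rose in D66 did not pass 4-fold, and the largest rises were in an endonuclease, a 2 5 oligoadenylate synthetase, the SNARE STX6 and 3 TROVE domain ribonucleoproteins. The largest falls included the like-named models of FKB16 2, THI4 and THIC, and the antenna and photosystem core lists had low medians. Of 9307 genes, 416 rose (208 named) and 523 fell (270 named), against 161 and 263 in D66. The median of all genes was 0.08, which upper-quartile scaling shifts by -0.20. The share of risen genes was 44.3%, and 34.9% under upper-quartile scaling (328 higher and 611 lower).

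The endonuclease (117978) rose from 6.05 to 516 RPKM (log2 6.20), a 2 5 oligoadenylate synthetase (152186) from 1.53 to 131 RPKM (5.71) and the Qc SNARE STX6 (160025) from 12.7 to 693 RPKM (5.66). A cyclin-like F box protein (178064) rose from 0.774 to 66.6 RPKM (5.25) and the zygote-specific LZY1B (449) from 7.97 to 297 RPKM (5.05). Of the TROVE domain ribonucleoproteins, 138565 rose from 5.95 to 198 RPKM (4.84), 134715 from 2.44 to 92.7 RPKM (4.77) and 39139 to 272 RPKM (4.57). A phosphopantothenate cysteine ligase (116788) rose from 3.92 to 103 RPKM (4.40), and a beta ketoacyl synthase (153976) was listed at 0 in replete and 21.5 RPKM in deprived ars11. Without a described function, 186256 rose from 5.46 to 381 RPKM (5.89) and 181875 from 7.83 to 411 RPKM (5.54).

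The largest fall was that of the immunophilin FKB16 2c (80367), from 238 to 3.13 RPKM (log2 -5.86), with the similar models FKB16 2a (195500; 184 to 2.46, -5.74) and FKB16 2b (195502; 162 to 2.08, -5.72). Of models named for thiamine synthesis, THI4a (185190) fell from 1682 to 29.5 RPKM (-5.79), THI4b (196899) from 1557 to 27.4 RPKM (-5.78), THICa (192720) from 74.2 to 0.639 RPKM (-5.52) and THICb (196900) from 72.1 to 0.615 RPKM (-5.50). These models share names and have similar values, and their sequences were not compared here, so how their reads are divided is uncertain. PRX1 (142363), a 2-cys peroxiredoxin, fell from 759 to 20.3 RPKM (-5.16) and an allene oxide cyclase (183696) from 399 to 12.8 RPKM (-4.86). The spliceosomal U5a (205814) was at 49.2 RPKM and listed at 0 after deprivation, as were the gene models without a name 180860 and 181249 (76.7 RPKM each in replete ars11).

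Sulfate uptake in ars11 had 1 of 7 genes at least 2-fold higher and 6 within (median 0.01, -0.16 under upper-quartile scaling; percentile 39.2). SLT1, SLT2, SULTR2 and AOT4, the 4 largest rises of this list in D66, lay below 5 RPKM in both ars11 libraries and did not enter. Over the 11 genes without this filter, 2 were at least 2-fold higher and 9 within (median -0.08). SULTR3 (206236) was at 6.74 and 29.5 RPKM. SLT1 (205502) was at 0.256 and 0.0489 RPKM and SLT2 (205501) at 1.46 RPKM in deprived ars11, and SULTR2 (150514) at 0.164 and 1.82 RPKM (1.28). Of the arylsulfatase and sulfonate list, 2 genes were measured and both lay within 2-fold (median 0.23), while ARS1 and TAUD1 lay below 5 RPKM and did not enter. In sulfate assimilation and cysteine synthesis, 2 of 16 genes were at least 2-fold higher, 6 lower and 8 within (median -0.59, percentile 0.63). SAT1a (205985) was at 14.3 and 40.4 RPKM and OASTL4a (183351) at 103 and 31.4 RPKM. Methionine and thiol genes were lower in 5 of 13 and higher in 1 (median -0.90): SAH1 (129593) fell from 952 to 82.7 RPKM (-3.51). The extracellular and cell wall list was lower in 18 of 42 and higher in 5 (median -0.58, but -0.28 under TMM and -0.27 under median-of-ratios scaling), with HRP3 (127246) rising from 3.02 to 37.6 RPKM (3.26). In sulfolipid and storage lipid, 8 of 16 were lower (median -1.01), and SQD2 (206163) fell from 15.6 to 1.53 RPKM (-2.71).

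The antenna and the photosystem core had the lowest medians of the 26 lists in this comparison. In the antenna, 20 of 27 genes were at least 2-fold lower, 15 of them 4-fold (median -2.36, percentile 0), and LHCBM5 (184775) fell from 2292 to 94.6 RPKM (log2 -4.58). In the photosystem core, 27 of 34 were lower, 19 of them 4-fold, and 2 higher (median -2.12): PSBS1 (196341) rose from 0.496 to 18.1 RPKM (3.67), while the electron carrier PCY1 (185915) fell from 8397 to 342 RPKM (-4.61) and FNR1 (195553) from 605 to 27.6 RPKM (-4.41). In carbon fixation, 16 of 58 were lower and 7 higher (median -0.40), and PRK1 (195910) fell from 693 to 33.5 RPKM (-4.33). Chlorophyll synthesis was lower in 17 of 25 (median -1.38), with CHLM (195575) falling from 82.4 to 11.2 RPKM (-2.78). Plastid ribosomal genes were lower in 18 of 36 (median -1.02), 1 of them at least 4-fold. In histones and cell cycle, 30 of 48 were lower and 7 higher (median -1.33): CYCB1 (206115) fell from 51.4 to 1.83 RPKM (-4.21), while a histone H4 model (163170) rose from 12.4 to 257 RPKM (4.27). Histone sequences are near-identical, so single models are uncertain.

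Of the 26 lists, 2 lay above the central range. Stress-related LHC genes were at least 2-fold higher in 4 of 8 and lower in 1 (median 0.97, percentile 97.7, and 95.2 at a filter of 20 RPKM). In proteasome, ubiquitin and autophagy, 30 of 75 genes were at least 2-fold higher and 1 lower (median 0.79, percentile 100); APG12 (194981), also at least 2-fold higher in D66, rose from 7.58 to 45.9 RPKM (log2 2.45), as did ATG8 (59275) from 107 to 980.0 RPKM (3.19). Redox defence had 19 of 80 higher and 18 lower (median 0.16, negative under upper-quartile scaling), with GSTS1 (193661) rising from 27.7 to 494 RPKM (4.11). Heat shock and chaperones had 19 of 96 higher and 17 lower (median 0.12, negative under upper-quartile scaling); an AAA ATPase chaperone (179044) rose from 24.9 to 455 RPKM (4.14). Flagellar genes had 288 of 347 within 2-fold, 46 lower and 13 higher (median -0.20), with FBB6 (188114) rising from 1.92 to 55.4 RPKM (4.27). The remaining lists had medians of 0.18 (cytosolic ribosomal), 0.10 (starch), 0.12 (polyphosphate and vacuole), 0.47 (hydrogenase and fermentation), -0.31 (phosphorus), 0.17 (nitrogen), -0.09 (gamete and zygote) and 0.42 (housekeeping). The cytosolic ribosomal, starch, polyphosphate and nitrogen medians turn negative under upper-quartile scaling. In this comparison SLT1, SLT2, SULTR2, AOT4, ARS1, TAUD1, FNR1, the histone H4 model, APG12 and ATG8 were named outside the naming rule, after the values were seen. Shorter alignments in the deprived ars11 lanes and the 0 h and 6 h sampling limit this comparison.

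**Figure D3:**
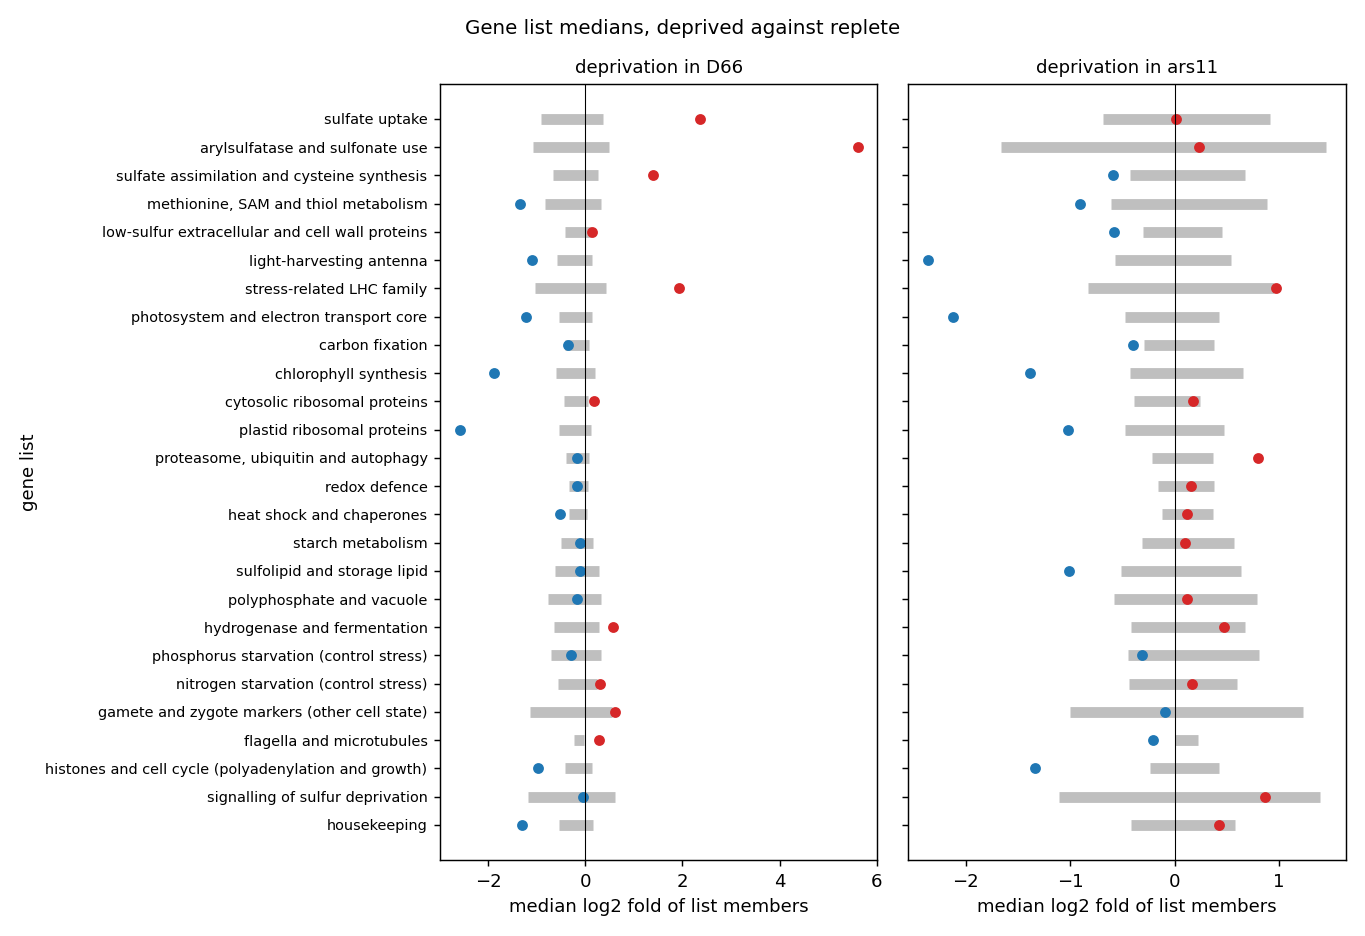
Median log2 change with deprivation for the gene lists in D66 and ars11 panels; dots are list medians (red positive, blue negative) and grey bars span the central range of random lists. Sulfate uptake stands at 2.37 in D66 (11 genes) and 0.01 in ars11 (7 genes past the filter; -0.16 under upper-quartile scaling), and plastid ribosomal proteins at -2.57 and -1.02.

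Whether the response of the wild type is also seen in ars11 was asked by comparing the responses. LHCBM9, ECP76 and TAUD1 rose in D66 and stayed within 2-fold at low values in ars11, while METE and FAP24, named here outside the naming rule after the values were seen, fell in both strains. Of 161 genes that rose in D66, 93 rose at least 4-fold less in ars11. In ars11, 59 of the 161 were at least 2-fold higher, 87 within 2-fold and 15 lower (median 0.38). Of 263 genes that fell in D66, 151 were at least 2-fold lower in ars11, 105 within and 7 higher (median -1.22). Over 9793 genes the Pearson r of the responses was 0.328, and genes are not independent. Of 8193 genes in both comparisons, 22 rose in both (3.22 expected of independent lists) and 78 fell in both (13.6 expected). Whether rises and falls differ in this was not tested. Genes chosen for a large rise in 1 library tend to show a smaller one elsewhere, and without replicates the size of this effect is not known.

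The 10 largest shortfalls in ars11 were ECP88 (137329), ARS1 (205496), LHCBM9 (184479; log2 difference -10.05), HAP2 (143696; -9.57), ECP76 (130684; -9.48), SBD1 (182845; -8.10), HAP1 (168785; -7.69), ECP 61 (119420; -7.67), ECP 56 (194201) and TAUD1 (127464; -7.43). ECP88 and ECP 56 were listed at 0 in both ars11 libraries and ARS1 in deprived ars11, so the sizes for these depend on the added 1 RPKM. SBD1, a selenium-binding protein, rose from 33.3 to 1375 RPKM in D66 (5.32) and fell from 36.1 to 4.41 RPKM in ars11 (-2.78). The 5 largest excesses were the actin-like NAP1 (168932; 7.18), the endonuclease (117978; 6.96), STX6 (160025; 6.03), the cyclin-like F box protein (178064; 5.93) and NRX2 (182094; 5.50), a nucleoredoxin. NAP1 fell from 31.2 to 3.23 RPKM in D66 (-2.93) and rose from 76.7 to 1479.8 RPKM in ars11 (4.25).

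**Figure D4:**
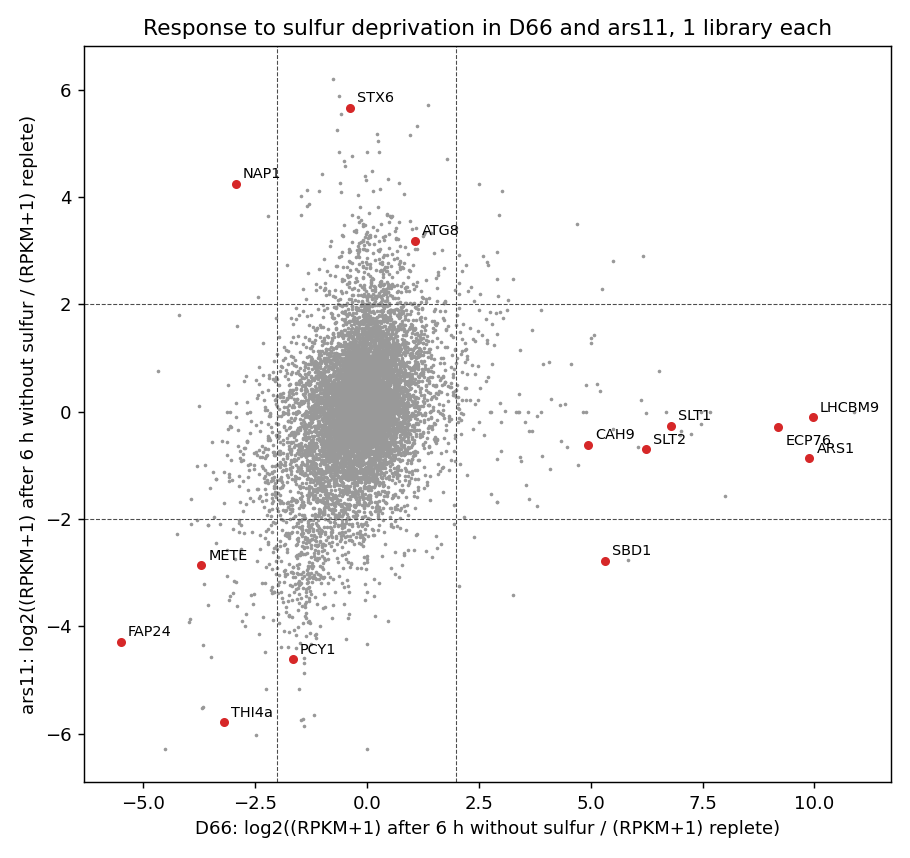
Log2 change with deprivation in D66 (horizontal) and in ars11 (vertical), 1 point per gene, with dashed lines at -2 and 2. LHCBM9 (9.96 in D66, -0.10 in ars11) and SBD1 (5.32, -2.78) lie far to the right, and STX6 (-0.37, 5.66) and NAP1 (-2.93, 4.25) lie high.

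How the strains differ before deprivation was asked by comparing replete ars11 with replete D66. The ferredoxin FDX5 and the pyruvate ferredoxin oxidoreductase PFR1 were higher in ars11. The sulfate transporter SLT1 and the small heat shock proteins HSP22E and HSP22F were lower. Of 8803 genes, 61 were higher (26 named) and 38 lower (20 named), and the median of all genes was 0.06. A pseudocount of 5 gives 28 and 11, a filter of 20 RPKM gives 38 and 14, and a pseudocount of 0.1 gives 59 lower. Over windows, 221 were higher with all lanes and 478 with D66 lanes 1 and 2 only, so the number of higher features depends on the D66 lanes used.

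FDX5 (156833), a ferredoxin, was at 5.07 RPKM in D66 and 367 RPKM in ars11 (log2 5.92), PFR1 (122198), the pyruvate ferredoxin oxidoreductase, at 0.322 and 33.1 RPKM (4.69), and the prolyl 4 hydroxylases 143800 at 0.581 and 26.8 RPKM (4.14) and 166317 at 4.92 and 62.8 RPKM (3.43). Spliceosomal RNA models were higher: U6a (205832; 56.9 and 940.3 RPKM, 4.02), U5b (205817; 2.13 and 49.2) and U5c (205821; 4.87 and 64.3, 3.48). U5g (205822), U5d (205818) and U5f (205812) were listed at 0 in D66 and at 41.9, 8.52 and 5.93 RPKM in ars11. How reads are divided between these like-named models is not known. Without a name, 194369 was at 8.14 and 974 RPKM (6.74), and 180860 was listed at 0 in D66 and at 76.7 RPKM in ars11.

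Among the genes lower in ars11, AOT4 (206105) was at 21.4 RPKM in D66 and 0.0601 RPKM in ars11 (log2 -4.40), the small heat shock protein HSP22E (190200) at 38.8 and 0.937 RPKM (-4.36), and SLT1 (205502) at 20.2 and 0.256 RPKM (-4.08). HSP22F (129088) was at 29.5 and 2.09 RPKM (-3.30), a TROVE ribonucleoprotein (134715) at 30.3 and 2.44 RPKM (-3.19), the protease DEG1C (196360) at 22.8 and 1.66 RPKM (-3.16), the epimerase NED1 (206212) at 20.9 and 1.78 RPKM (-2.98) and LCA1 (186846) at 41.7 and 5.05 RPKM (-2.82). PHC18 (196031), a cell wall protein, was at 15.9 RPKM and listed at 0 in ars11, as was a haem peroxidase (194674; 15.6 RPKM in D66). Unnamed 150931 was at 71.9 and 0.960 RPKM (-5.22) and 183469 at 18.6 and 0.232 RPKM (-3.99). In sulfate uptake, 5 of 10 genes were at least 2-fold lower and 0 higher (median -0.88, percentile 0); SLT2 (205501) was at 16.8 RPKM in D66 and lower in ars11 (-2.16).

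Other lists lay mostly within 2-fold. The arylsulfatase and sulfonate list had 1 of 3 lower (median -0.69) with TAUD1 (127464) at 10.1 and 0.906 RPKM, and assimilation had 2 of 16 lower (median -0.31, percentile 1.22). Carbon fixation had 9 of 57 higher and 4 lower (median 0.18, percentile 99.5), with LCI1 (55019) at 149.7 and 843 RPKM (log2 2.48). The 9 all carry LCI, CCP or CAH names. The 4 are RPE1 (135614; -1.25), CAH9 (196834; -1.11), SBP1 (182359; -1.09) and the rubisco activase RCA1 (128745; -1.03). Histones and cell cycle had 9 of 43 higher and 2 lower (median 0.63, percentile 100). Hydrogenase and fermentation had 7 of 18 higher (median 0.31), with HYD1 (183963) at 35.9 and 130.1 RPKM. Chlorophyll synthesis and plastid ribosomal proteins had medians of -0.45 and -0.50 with 22 of 25 and 34 of 36 within 2-fold. Heat shock and chaperones had 86 of 93 within (median -0.23) and flagella 334 of 340 within (median 0.25). The antenna (median 0.01, negative under each other scaling) and photosystem core (33 of 33 within, median -0.01) held near 0. The other medians lay between -0.45 (methionine and thiol) and 0.37 (gamete and zygote). Of these, methionine and thiol (percentile 0.55), sulfolipid and storage lipid (-0.29, percentile 0.68) and housekeeping (-0.29, percentile 0.96) lay below the central range. In this comparison SLT2, HYD1, CAH9, SBP1 and RCA1 were named outside the naming rule, after the values were seen. A difference between 1 culture of each strain, whose reads also differ in trimmed lengths, cannot be assigned to the lesion.

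How the strains differ after deprivation was asked by comparing deprived ars11 with deprived D66. The actin-like NAP1, the SNAREs STX6 and VAMP74 and the nucleoredoxins NRX2 and NRX3 were higher in ars11, as was the median of the proteasome, ubiquitin and autophagy list. LHCBM9, SLT1, SLT2 and TAUD1 were lower. This comparison and the D66 response share the deprived D66 library, so a gene with a high value there tends to appear both risen in D66 and lower in ars11. Of 8988 genes, 528 were higher (264 named) and 293 lower (167 named). The median of all genes was 0.31, which TMM, median-of-ratios and upper-quartile scaling shift by -0.24, -0.24 and -0.40. The share of higher genes was 64.3% and became 52.1% (402 higher and 369 lower), 52.0% (402 and 371) and 42.6% (324 and 437).

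NAP1 (168932) was at 3.23 RPKM in D66 and 1479.8 RPKM in ars11 (log2 8.45), STX6 (160025) at 3.90 and 693 RPKM (7.15), LZY1B (449) at 1.35 and 297 RPKM (6.99) and the nucleoredoxin NRX2 (182094) at 4.68 and 701 RPKM (6.95). FDX5 (156833) was at 0.844 and 174 RPKM (6.57), the endonuclease (117978) at 5.09 and 516 RPKM (6.41), a von Willebrand factor type A protein (194003) at 2.98 and 335 RPKM (6.40), NRX3 (141568) at 1.54 and 149.7 RPKM (5.89), PFR1 (122198) at 1.14 and 103 RPKM (5.60) and the R SNARE VAMP74 (136188) at 6.79 and 321 RPKM (5.37). Unnamed 173319 was at 3.22 and 298 RPKM (6.15) and 191592 at 0.138 and 54.2 RPKM (5.60).

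Lowest in ars11 were LHCBM9 (184479; 21455 and 3.05 RPKM, log2 -12.37), SLT1 (205502; 2341 and 0.0489, -11.12), TAUD1 (127464; 1417 and 0.413, -9.97), HAP3 (182794; 1456 and 0.644, -9.79), ECP76 (130684; 899 and 0.0767, -9.71), HAP2 (143696; 1044 and 0.336, -9.61) and SLT2 (205501; 1339 and 1.46, -9.09). ARS1 (205496), ECP88 (137329) and ECP 56 (194201) were at 2717, 2295 and 317 RPKM in D66 and listed at 0 in ars11. Unnamed 150931 was at 3279.5 and 0.567 RPKM (-11.03) and 183469 at 1482 and 0.220 RPKM (-10.25). In sulfate uptake, 8 of 11 genes were at least 4-fold lower and 1 was 2-fold higher (median -2.63, percentile 0), and without AOT4 the median was -2.62. In sulfate assimilation, 11 of 16 were lower and 0 higher (median -2.29), with OASTL4b (205986) at 894 and 25.9 RPKM (-5.06). The arylsulfatase and sulfonate list had 5 of 6 lower (median -5.70).

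Photosynthesis genes were also lower in ars11: 15 of 28 antenna genes (median -1.06) and 16 of 32 photosystem core genes (2 higher). Plastid ribosomal genes were higher in 13 of 36 (median 0.84, percentile 98.3), PRPL7/L12 (99271) being at 52.0 and 277 RPKM (log2 2.39). Proteasome, ubiquitin and autophagy had 39 of 74 higher and 0 lower (median 1.05, percentile 100). Housekeeping had 16 of 28 higher and 0 lower (median 1.27, percentile 100), with EIF3D (181144) at 14.9 and 119 RPKM (2.92). In that list RACK1 (105734; 0.72) and TUB1 (129876; -0.06) lay within 2-fold. Extracellular and cell wall genes were lower in 13 of 44 (median -0.45), flagellar genes in 39 of 343 (median -0.28) and sulfolipid and storage lipid genes in 3 of 12, with SQD1 (27658) at 336 and 19.4 RPKM (-4.05). Methionine and thiol genes were higher in 4 of 13 (median 0.23, -0.14 under upper-quartile scaling). Heat shock and chaperones had 30 of 95 higher (median 0.41) and redox defence 22 of 80 (median 0.20, negative under each other scaling). The remaining medians were near the median of all genes or below it: carbon fixation -0.04, chlorophyll 0.02 (negative under each other scaling), starch 0.26 and polyphosphate 0.26 (both negative under upper-quartile scaling), nitrogen -0.13, phosphorus -0.25, histones -0.07, hydrogenase -0.13, gamete -0.22, cytosolic ribosomal -0.04, stress LHC -0.00. The signalling median was 0.93. The carbon fixation median covers opposite changes of its members. PRK1 (195910; -3.67), GAP3 (129019; -2.97) and TRK1 (141319; -2.76) were lower in ars11, while LCI1 (55019; 3.26) and CAH4 (24552; 2.97) were higher. EIF3D, AOT4, PRK1, GAP3, TRK1, LCI1, CAH4, RACK1 and TUB1 were named here outside the naming rule, after the values were seen. The lower depth of ars11, its other trimmed lengths and a single culture of each strain limit what this comparison can assign.

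**Figure D5:**
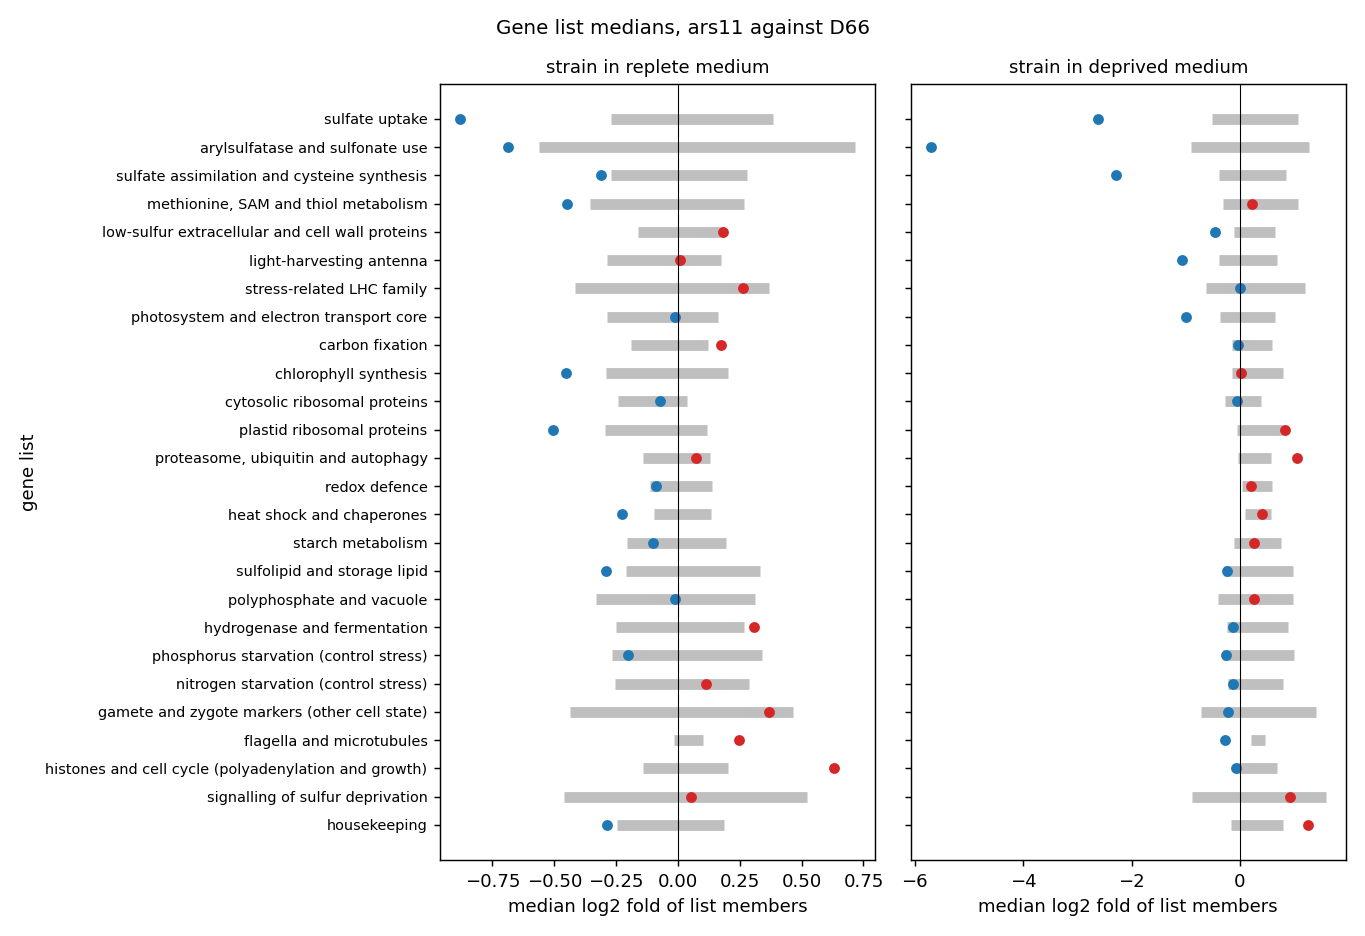
Median log2 difference of ars11 against D66 for the gene lists, in replete and deprived panels; dots are list medians (red positive, blue negative) and grey bars span the central range of random lists. Sulfate uptake lies at -0.88 and -2.63, and proteasome, ubiquitin and autophagy at 0.07 (negative under TMM and median-of-ratios scaling) and 1.05.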

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

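The tests of explanations named in this part were all chosen only after the result was seen, and the scalings of lists and gene counts were planned.

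The lists below lay outside the central range in both strains with medians of opposite sign, and each rests on 1 library per group. Other lists of opposite sign lay inside that range in 1 strain or both. Housekeeping was among these, at -1.29 in D66 and 0.42 in ars11 (percentiles 0.01 and 92.0). Sulfate assimilation and cysteine synthesis had a median log2 change of 1.40 with deprivation in D66 and -0.59 in ars11; the difference was not tested. Extracellular and cell wall proteins had 0.13 and -0.58, and the difference was not tested. Under TMM these were 0.32 and -0.28 and under median-of-ratios scaling 0.32 and -0.27, where the ars11 median lay inside the central range (percentiles 3.62 and 3.71). At a filter of 20 RPKM the medians of both strains lay inside it (percentiles 96.2 in D66 and 10.8 in ars11). In D66 this list was mixed, with most genes within 2-fold. Flagella and microtubules had 0.29 and -0.20, and 0.46 and -0.39 under upper-quartile scaling, and the difference was not tested. Most flagellar genes lay within 2-fold in both strains.

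Among single genes, 5 were at least 4-fold higher in deprived D66 and at least 4-fold lower in deprived ars11, against 4.82 expected of independent lists; the difference was not tested. They are SBD1 (182845; 33.3 to 1375 RPKM in D66, 36.1 to 4.41 in ars11), 182073 (1.37 to 11.5, 5.21 to 0.235), 185846 (listed at 0 and 8.61, 9.63 and listed at 0), 187452 (12.3 to 54.6, 8.45 and listed at 0) and 190325 (2.92 to 222.5, 9.33 to 0.524). In the other direction were 2 genes, against 9.06 expected: NAP1 (168932; 31.2 to 3.23 RPKM, 76.7 to 1479.8) and 195183 (325 to 59.5, 225 to 997); the difference was not tested.

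More genes were at least 4-fold apart between media in ars11 (939) than in D66 (424), a ratio of 2.21 and of 2.22 over windows. Shorter alignments in the deprived ars11 lanes are unlikely to be the whole cause, since the ratio over windows was 2.29 with 35-base alignments only. Lower depth might account for part of it, since the ratio was 1.70 with D66 lanes 1 and 2 thinned to the ars11 reads, but it was already 1.77 with these lanes before thinning. The ratio was 2.35 with TMM factors, but this cannot decide on a scaling set by a few abundant transcripts. With 1 factor per library, rises are largely traded for falls, so the totals change little (390 in D66 and 915 in ars11). The snrk2.1 lesion and any other difference between the cultures cannot be told apart, because there is 1 library per group.

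D66 lanes 1 and 2 differ from the other D66 lanes. Counting noise is unlikely to be the cause, with a mean chi-square per degree of freedom of 4.43 (median 1.06) in the D66 library where it was lower. A different make-up of aligned lengths is also unlikely, since 96 windows were at least 4-fold apart in replete D66 with 35-base alignments only, against 89 with all alignments. A preparation or run difference shared by both media is a possible cause, since the lane set differences in the 2 media had a Pearson r of 0.410 over windows.

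Low-oxygen marker genes were higher in replete ars11 (9 of 11 at least 2-fold, median 2.71). Less oxygen in that culture could be behind it, but the 17 other hydrogenase and fermentation genes had a median of 0.12 at percentile 76.8, which leaves it open. Among these 17, HYD1 (183963; 1.83), HYDEF (128256; 1.82), HYDG (196226; 1.65), HYD2 (24189; 1.42) and PFL1 (146801; 1.11) were at least 2-fold higher. A zinc alcohol dehydrogenase (190503; -1.23) was lower, and most of the others lay within 2-fold. These single genes were picked after the values were seen. Copper deficiency could also raise some of the low-oxygen marker genes. The 4 measured copper-responsive genes had a median of 0.88 with 2 of them at least 2-fold higher. CYC6 (193170), also in this list, lay below 5 RPKM and did not enter. It was at 0.177 RPKM in replete D66 and 3.93 RPKM in replete ars11 (log2 2.07), low values that depend on the added 1 RPKM. Oxygen and copper cannot be told apart here, because neither was measured and the lists are short.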

How the results depend on the processing

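The lane subsets of D66, their thinning and the lists without members named as another protein (HAP2 below) were chosen only after the result was seen. The other settings below were planned. No paired analysis was possible because each group holds 1 library. Gene values recounted from the lane files and values from whole reads were not run.

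A pseudocount of 5 gave 99 higher and 139 lower genes for deprivation in D66 (161 and 263), 209 and 217 in ars11 (416 and 523), 28 and 11 between strains in replete medium (61 and 38), and 260 and 154 in deprived medium (528 and 293). A larger pseudocount shrinks folds of low values by construction. A pseudocount of 0.1 gave 59 lower in replete medium. A 2-fold size rule gave 588 and 1334, 1606 and 1475, 416 and 239, and 2095 and 978 in the same order, larger by construction. Asking for 20 RPKM gave 274 lower in deprived ars11, 38 higher and 14 lower between strains in replete medium, and 193 lower in deprived medium, since fewer genes enter. Upper-quartile scaling gave 324 higher and 437 lower between strains in deprived medium. It shifts the median of all genes by -0.40, so fewer higher and more lower genes follow by construction.

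For genes that rose in D66 but at least 4-fold less in ars11 (93), the 2-fold size rule gave 323, and letting 2-fold rises enter gave 151. The Pearson r between responses (0.328) was 0.314 with a pseudocount of 0.1, 0.334 with 5, 0.315 without filter, 0.338 at 20 RPKM and 0.355 over genes at least 2-fold changed in either strain; the cause was not tested. Over windows, 221 were at least 4-fold higher in replete ars11, against 478 with D66 lanes 1 and 2 only and 501 when these were also thinned; the cause was not tested.

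Of list medians, 857 stayed close and 161 moved. Some lists outside the central range came inside it under a setting; the cause was not tested. For deprivation in D66 these were extracellular proteins (percentile 96.2 at 20 RPKM), nitrogen (91.7 at 20 RPKM, 97.0 by symbol only) and gamete and zygote (95.8 without filter, 82.5 without HAP2). In ars11 they were extracellular proteins (10.8 at 20 RPKM, 3.62 with TMM), stress LHC (95.2 at 20 RPKM) and sulfolipid (7.43 at 20 RPKM). Between strains in replete medium they were arylsulfatase (4.23 without filter), assimilation (3.86 by symbol only), carbon fixation (95.8 without filter, 87.9 at 20 RPKM, 94.7 unmatched), sulfolipid (8.48 by symbol only) and hydrogenase (97.3 unmatched). In deprived medium it was plastid ribosomal proteins (96.0 at 20 RPKM). Histones and cell cycle went to percentile 50 without filter in D66, in ars11 and between strains in replete medium, where many of its models at 0 enter.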

Other observations

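The 7 gene groups in this part, like the tests on them, were chosen only after the result was seen. The single genes given as examples were picked in the same way. They show what stood out and are not independent of the values they describe.

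Membrane traffic genes stood out in ars11. Of 47 measured SNARE, ESCRT and retromer genes, 26 were at least 2-fold higher in deprived ars11 and 0 lower (percentile 100), against 2 of 46 higher in D66 (median log2 0.25). Examples besides STX6 are YKT6 (195465; 31.8 to 277 RPKM) and VPS60 (143567; 28.0 to 235). TROVE domain and 2 5 oligoadenylate genes rose in 5 of 5 in ars11 (median 4.77) and lay within 2-fold in 4 of 4 in D66 (median -0.56). The fifth, 152186, was at 0.962 and 4.06 RPKM in D66. The 3 TROVE genes start lower in replete ars11 than in replete D66 (138565 -2.25, 134715 -3.19, 39139 -1.56). The heat shock protein 22 family was mixed (median 3.18 with deprivation in ars11). Of 3 measured genes, HSP22E and HSP22F rose with deprivation in ars11 (log2 3.18 and 3.25), but HSP22A (134508) went from 6.83 to 1.24 RPKM (-1.81). Between strains in replete medium HSP22E and HSP22F were lower in ars11 (-4.36 and -3.30), and HSP22A lay within 2-fold (-0.31).

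U snRNA gene models were higher in replete ars11 in 9 of 11 (median 2.79) and had a median of -0.98 with deprivation in ars11. How reads of such copies were placed is not known. The histone and cell cycle list was set in advance as 1 on polyadenylation and growth. It too was high in replete ars11 against D66 (median 0.63, percentile 100). Whether the libraries of the 2 strains differ in preparation was not tested, so these values cannot be assigned to strain. Low-oxygen markers had a median of 2.71 in replete and 1.75 in deprived ars11 against D66, copper-responsive genes 0.88 and 1.76, and low CO2 inducible genes 1.86 and 2.11, with CAH4 (24552) at 368 and 1614 RPKM in replete D66 and ars11. The 10 low CO2 genes are a selection: the other measured genes named low CO2 inducible had medians of 0.36 (27 genes, 6 at least 2-fold higher and 0 lower) and 0.81 (28 genes, 11 higher and 1 lower).

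In the authors' deposited table, the sequencing fold of wild-type genes had a Pearson r of 0.890 with the column marked Q at 6 h over 29 genes, 28 of them with the same sign. In the authors' deposited table, the wild-type r with columns marked M was 0.384 at 1 h, 0.437 at 6 h and 0.359 at 24 h (319, 837 and 547 genes). For the mutant against the wild type with sulfur, the authors' deposited table gave an r of 0.756 with Q at 0 h (29 genes) and -0.0166 with M at 0 h (934 genes, 442 with the same sign). Without sulfur, the authors' deposited table gave 0.918 with Q at 6 h (29 genes), and 0.215, 0.336 and 0.123 with M at 1, 6 and 24 h (795, 577 and 780 genes). By the p-values of the authors' deposited table, 21 of the 424 genes at least 4-fold apart in D66 had p above 0.05, 50 of 939 in ars11, 17 of 99 between strains in replete medium and 41 of 821 in deprived medium.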
